A study of Drosophila melanogaster with 15 samples.

How the data were processed

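Polyadenylated RNA was taken from larval brains at 3 brains per library, and libraries were made with the NEBNext poly(A) isolation and Ultra II RNA kits with 13 cycles of amplification, per the labels' protocols. The deposited table held whole-number read counts per gene that the authors had not normalized, for 8990 genes and 15 libraries. Reads were trimmed with Trim Galore, aligned with STAR 2.7.10a to dm6 and counted with featureCounts, per the submitters' processing notes. The strand setting, the treatment of reads that match several places and the filter on genes were not given in the sources used here. The smallest mean count of any gene was 27, so genes with few reads were not analysed here. Chromosomes, coordinates and symbols came from the reference annotation of the same assembly, matched by gene identifier, with a symbol for 8939 genes and none for 51, which were counted and not named. Because strand and multiple matches were not given, genes with near-identical copies, overlapping neighbours or antisense partners are uncertain.

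Groups were taken from the genotype labels and replicate numbers from the batch labels. The T2L genotype was matched by elimination. Libraries of a group came from different days, per the series design text, so p-values measure the spread between days and pools of brains. Replicates were compared before averaging, and within every group the squared difference between 2 libraries was 61.9 to 225 times the sampling variance, so none was counted as a repeat of another.

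Changed genes were found with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust dispersion, with TMM scaling, filterByExpr by group (8981 genes tested, 9 removed), 1 mean per group over all 15 libraries, and no covariate. P-values are two-sided, adjusted by the method of Benjamini and Hochberg, and called under 0.05. Biological variation had a coefficient of 24.9%. CPM values use TMM-scaled library sizes and are given as mean and SD over 3 libraries. Lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01 between genes and again with a correlation estimated from the data, adjusted over lists. Of 30 lists fixed from textbook knowledge, 29 had at least 3 measured genes. They cover proteasome, heat shock, endoplasmic reticulum, autophagy, stress, mitochondria, glycolysis, ribosome, cell cycle, brain cell types, hormones, immunity and dosage compensation, and markers of fat body, muscle, hemocytes, salivary gland and cuticle, eye-antennal disc, and ring gland and trachea. Some lists share genes, such as chinmo in 2 of them. For each list genes were also counted after adjustment over the list alone. The test fry, which asks whether the genes of a list move one way without comparing them with other genes, gave adjusted p = 0.0114 for proteasome, 0.00456 for nuclear oxidative phosphorylation and 0.0127 for glycolysis in CDXX, and 0.207 for proteasome in T2L. Some lists that camera did not call were under 0.05 in fry. Among these in T2L were the immune list (fry adjusted p = 0.0084) and the dosage compensation list (fry adjusted p = 0.0185). Those of CDXX include some marked below. Chromosome arms were tested with camera in the same way.

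Genes were named by a rule set before the data were examined, as were lists, tests and the first set of alternatives. It took the 6 largest rises and 6 largest falls of each main comparison among changed genes with a mean of at least 5 CPM and no overlap between the groups. It added 5 each way among genes changed in both comparisons, 4 each way in the comparisons of CDXY and C2L with Oregon and in the difference, where overlap between groups was allowed, and up to 4 genes with the lowest adjusted p per list. The Hsp70 copies and stv in CDXX were named after their values were seen.

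The batch labels mark shared days and so pair libraries across groups. As a check, the deviations of libraries from their group means had a median correlation of 0.13 within a batch (16 of 30 pairs over 0.1) and −0.066 between batches (17 of 60). The fit with batch as a block was kept as an alternative.

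The scripts were tested on simulated counts for 8981 genes drawn from negative binomial distributions with the real gene means and dispersions, with 70, 70 and 60 genes changed by 1.5, 2 and 4-fold. For CDXX against CDXY they called 25.7%, 67.1% and 93.3% of these, and 2.31% of calls were false. For T2L against C2L the shares were 41.4%, 72.9% and 96.7%, with 4.08% false. In that setting smaller changes than 1.5-fold would often be missed at this number of libraries. The simulation drew genes independently, took these changed genes from those with higher counts, and changed far fewer than the 3942 called in CDXX. Its shares therefore need not hold for the real comparisons.

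Alternatives set beforehand were size factors of DESeq2 within edgeR, the Wald test of DESeq2 1.42.0, no filter on low counts, at least 10 counts in 3 libraries, factors from genes off X and 2L, the batch block, a fit of the compared groups alone, a fold change of at least 1 on the log2 scale, lists without genes on X and 2L, and leaving out each library in turn. Covariates for the ecdysone list and for ring gland genes (spok, sad and dib) were chosen after seeing the data. Floors use 3 counts over a group without counts, and they and the Wilson intervals at 95% cover counting error only. The Y-linked list had 1 measured gene and was not tested.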

Results

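The series measured polyadenylated RNA in brains dissected from female late L3 larvae of Drosophila melanogaster, and its title concerns small brains, protein quality control and mitochondria under chromosomal instability. It held 15 libraries in 5 groups of 3, each library made from 3 brains, with the replicates of a group collected on different days and carrying the batch labels 4, 5 and 6. CDXY larvae carried an attached X chromosome, C(1)DX, with a Y chromosome and served as the control for CDXX larvae, which carried C(1)DX with a free X and so 3 copies of X against 2. C2L larvae carried the compound left arm of chromosome 2, C(2L)SH1, and served as the control for T2L. The label T2L was read as C(2L)SH1/+, the one stated genotype left after the other labels were matched, which holds 3 copies of the arm 2L against 2. Oregon is a standard laboratory strain. CDXY and C2L brains were taken 5 days after egg laying and CDXX and T2L brains 8 days after, so age and genotype differ together in both main comparisons, and the age of the Oregon larvae was not given. Total counts ran from 22.9 to 28.3 M per library over 8990 genes.

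CDXX against CDXY asks how larval brains with an extra X differ from those with a Y chromosome instead, taken at another age. An effect of the extra X cannot be told apart from these. X-linked genes stood 1.44-fold above the other genes in CDXX relative to CDXY, a difference of medians of 0.53 on the log2 scale, where 3 copies against 2 would give 0.585. Of 1564 X-linked genes tested, 901 rose, 38 fell and 86.4% had a log2 fold change above 0. Within batches the difference of medians was 0.524 ± 0.038 (SD, n = 3 batches), and it passed the test against other genes with a preset correlation (camera adjusted p = 1.76e-29) and with an estimated one (adjusted p = 4.26e-06). The largest autosomal arms had medians between −0.09 and −0.04. Genes on chromosome 4 had a median of −0.19 (camera adjusted p = 0.0359, and adjusted p = 0.594 with an estimated correlation), and 24 of its 87 genes fell while 6 rose. The share that fell there, 27.6%, was near the 22.2% to 26.4% of the large autosomal arms. In CDXX against Oregon chromosome 4 did not pass (camera adjusted p = 0.21).

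**Figure D1:**
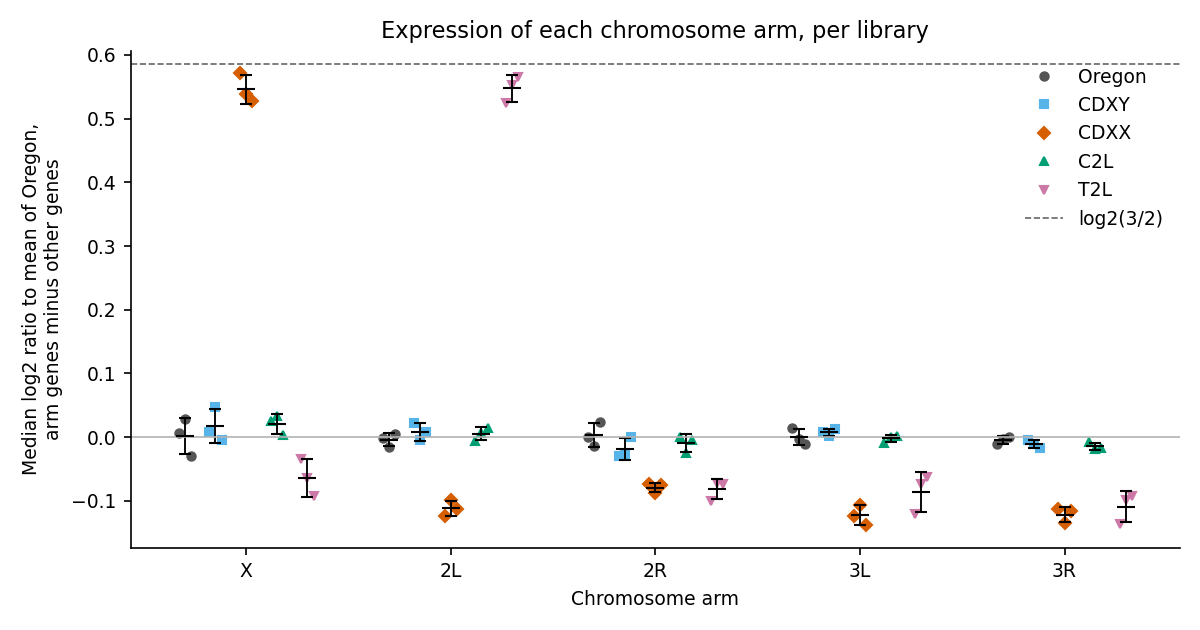
Median log2 expression of the genes on each chromosome arm minus that of all other genes, per library relative to the Oregon mean, for the 5 groups; each point is a library, the bars show the group mean and its SD over 3 libraries, and the dashed line marks the log2 ratio of 3 copies to 2. X stands near 0.5 in the 3 CDXX libraries (0.528 to 0.571) and 2L in the 3 T2L libraries (0.524 to 0.565), and in the other groups both arms lie between −0.123 and 0.0468. In each CDXX library 2L lies below 0, as X does in each T2L library, and so do 2R, 3L and 3R in all of these. The other genes include the raised arm, so the measure itself pulls the remaining arms below 0.

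Of 8981 genes tested, the genes changed in CDXX against CDXY numbered 3942 (edgeR QL, BH adjusted p under 0.05). Of these 2071 were higher and 1871 lower, and 957 changed by at least 2-fold. Off the X chromosome, 1170 genes rose and 1833 fell among 7417 tested. Scaling factors taken only from genes off X and 2L called 3846 genes, 2484 higher and 1362 lower, so that 64.6% of calls were higher instead of 52.5%.

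The largest rises were in CG14277 (0.322 ± 0.347 CPM in CDXY and 48.7 ± 33.3 in CDXX, SD, n = 3), the transporter-family gene CG10226 (0.961 ± 0.593 to 82.6 ± 48.5), the cytochrome P450 gene Cyp28a5 (0.573 ± 0.61 to 24.8 ± 1.35), CG5162 and CG9743. CG14277 (FBgn0032008, 2L, 8242486 to 8243426) rose by 7.21 on the log2 scale with a standard error of 1.3 (edgeR QL adjusted p = 0.00134). CG5773 was also among them, but its rise rested on CDXX replicate 6, without which its adjusted p was 0.123. Among the largest falls were ImpE2, a gene named for its induction by ecdysone (409 ± 495 to 11.1 ± 12.5 CPM), the ecdysone-regulated repressor Blimp-1 (37.4 ± 17.9 to 1.1 ± 0.503), the chitinase Cht5 (28.2 ± 9.94 to 1.37 ± 2.02), Jhbp2 and the serpin Spn100A. The call of ImpE2 in CDXX against CDXY ended without CDXY replicate 4 (adjusted p = 0.0669) or CDXX replicate 4 (adjusted p = 0.0591). CG34296 was at 40.8 ± 41.9 CPM in CDXY and had no count in CDXX, which makes it at least 990-fold lower against a floor of 3 counts over the group. Its CDXY libraries held 84, 0.368 and 38 CPM, and without the highest the bound was 465-fold.

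Proteasomes degrade proteins, and chaperones fold them in the cytosol and the endoplasmic reticulum. In CDXX, of 32 proteasome subunits, 24 fell, none rose and 8 were not called, with 26 lower when adjusted over the list alone. Rpn2, a scaffold subunit of the base of the regulatory particle, went from 397 ± 17.5 to 253 ± 31.1 CPM (SD, n = 3), Rpn1 from 359 ± 15.1 to 213 ± 40.6 and the ATPase Rpt2 from 241 ± 11.1 to 152 ± 23.3. The list median was −0.51 (camera adjusted p = 1.51e-07, and adjusted p = 0.63 with an estimated correlation). Chaperones of the endoplasmic reticulum also fell, with 9 of 18 genes of the unfolded protein response list lower and 1 higher (median −0.33, camera adjusted p = 0.00067, and adjusted p = 0.63 with an estimated correlation). Gp93, an Hsp90 of that compartment, went from 628 ± 35.4 to 367 ± 17.9 CPM and calreticulin, Calr, from 1160 ± 121 to 732 ± 62.

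Of 21 cytosolic and nuclear heat shock proteins, 11 fell, 7 rose and 3 were not called, and the counts adjusted over the list alone were the same. The small heat shock protein Hsp23 went from 2700 ± 500 to 773 ± 272 CPM (SD, n = 3), with an adjusted p of 0.00075 in the edgeR QL test, and Hsp110 from 466 ± 19.1 to 288 ± 42.5. The list median was −0.37 and its mean −0.09 (camera adjusted p = 0.0313, and adjusted p = 0.63 with an estimated correlation). With the ecdysone list as a covariate the heat shock median was −0.242, with 0 genes higher and 0 lower. That fit left 416 calls over all genes. The fall of these genes therefore cannot be told apart from hormone stage. Among the 7 that rose, looked at one by one after the values were seen, stv, a BAG-family cochaperone, lay between 40.4 and 50.4 CPM in the 3 CDXX libraries and between 12.8 and 18.5 in CDXY. The other 6 were near-identical Hsp70 copies, between which reads cannot be divided with certainty, and their rise rested on CDXX replicate 4, with Hsp70Aa at 58.4 CPM there and at 4.32 and 7.05 in the other CDXX libraries. Without that library the Hsp70Aa log2 fold change was 0.10 (adjusted p = 0.874), and the list was not called without CDXX replicate 5 (adjusted p = 0.163), CDXX replicate 6 (adjusted p = 0.107) or CDXY replicate 4 (adjusted p = 0.0679).

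Cells under stress can also turn to autophagy, DNA repair or antioxidant enzymes. Of 24 autophagy and lysosome genes 4 rose and 6 fell, with the X-linked Atg8a, the ubiquitin-like protein of autophagosomes, going from 280 ± 12.8 to 431 ± 12.8 CPM (camera adjusted p = 0.596 for the list). In the integrated stress response list 7 of 18 rose and 2 fell (camera adjusted p = 0.245, fry adjusted p = 0.00456). Those that rose included the transcription factor Xrp1 (217 ± 39.3 to 591 ± 90.3 CPM) and its partner Irbp18 (9.06 ± 1.43 to 14.9 ± 1.91). Of 23 genes of p53, DNA repair and apoptosis, 8 rose, such as mre11 (25.2 ± 3.41 to 55 ± 11.3). In the same list 6 fell, such as the caspase Dcp-1 (66.2 ± 8.18 to 35.5 ± 6.71) and the caspase inhibitor Diap1 (camera adjusted p = 0.714 for the list). In the JNK and JAK/STAT list 6 of 13 rose and 1, the kinase bsk, fell (camera adjusted p = 0.279, fry adjusted p = 0.005). Glutathione and oxidative stress genes passed, with 11 of 22 higher, 12 when adjusted over the list alone, and none lower (median 0.71, camera adjusted p = 0.00168, and adjusted p = 0.63 with an estimated correlation). GstE1 went from 11 ± 4.41 to 67.4 ± 8.71 CPM, and it belongs to a cluster of similar genes whose reads may be split.

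Mitochondria and glycolysis supply the energy of the cell, and 4 fixed lists cover them. Of 67 nuclear genes of oxidative phosphorylation, 37 rose, 40 when adjusted over the list alone, none fell and 30 were not called. All 11 X-linked members rose, such as the complex I subunit ND-20 (84.5 ± 2.59 to 167 ± 18.1 CPM, SD, n = 3), and so did 26 members elsewhere. The list median was 0.32 (camera adjusted p = 1.17e-08, and adjusted p = 0.63 with an estimated correlation), and the 42 members off X and 2L passed on their own (camera adjusted p = 0.00159). Of the 13 mitochondrially encoded genes 4 rose and none fell (camera adjusted p = 0.0766), with mt:ND6 at 19.1 ± 1.81 and 37 ± 6.8 CPM but not called without CDXX replicate 5 (adjusted p = 0.0576) or CDXY replicate 4 (adjusted p = 0.0611). In the mitochondrial quality control list 6 of 17 rose, among them the X-linked Pink1 (60.8 ± 3.04 to 124 ± 10.6), Marf and Hsp60A, and 2 fell (camera adjusted p = 0.102, fry adjusted p = 0.0114). Of 13 genes of glycolysis and lactate metabolism, 12 rose, all 13 when adjusted over the list alone. Lactate dehydrogenase, Ldh, went from 19.6 ± 4.29 to 204 ± 130 CPM, hexokinase A, Hex-A, from 138 ± 26.9 to 671 ± 156 and Pgi from 146 ± 44.4 to 594 ± 139. The glycolysis median was 1.4 (camera adjusted p = 7.7e-05, and adjusted p = 0.63 with an estimated correlation). Of 81 cytosolic ribosomal protein genes 43 rose, 51 when adjusted over the list alone, and 1 fell, and 69 rose with factors from genes off X and 2L. All 14 X-linked members were among the 43 (median 0.32, camera adjusted p = 1.01e-09, and adjusted p = 0.63 with an estimated correlation).

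The steroid hormone ecdysone times larval development. Of 23 ecdysone genes, 13 fell in CDXX against CDXY and 4 rose (median −0.84, camera adjusted p = 0.0182, and adjusted p = 0.63 with an estimated correlation), with the early response gene Eip75B going from 805 ± 170 to 342 ± 66.3 CPM (SD, n = 3). The nuclear receptor gene ftz-f1, of the following stage, rose by 1.78 on the log2 scale. With the mean log2 expression of this list as a covariate, added after the list was seen to vary, the genes changed in CDXX went from 3942 to 416, and the median of the glycolysis list from 1.42 to 0.04. The 416 ranged from 4 to 446 when each library was left out. Of those 416 genes, 272 lay on X, of which 271 were higher. The difference of medians between X and other genes stayed at 0.53 in that fit, so calls on X were lost while the folds as a group were not.

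Cell type lists of the brain did not pass in CDXX. Cell cycle and mitosis genes counted 5 higher and 3 lower of 37 (camera adjusted p = 0.879). Neuroblast markers counted 4 higher and 5 lower of 25, with a median of 0.11 and a test direction downward (camera adjusted p = 0.786), and nerfin-1 went from 457 ± 73.2 to 208 ± 43.3 CPM. In the temporal factors of neuroblasts 4 of 15 rose and 2 fell, with a median of −0.12 and a mean of 0.10 (camera adjusted p = 0.92), among them the early factors Imp (405 ± 33.4 to 875 ± 146 CPM, on X) and cas (49.7 ± 24.6 to 207 ± 110). Neuron and synapse markers had 5 higher of 30, none lower (camera adjusted p = 0.617), with the X-linked sodium channel para at 169 ± 57.6 and 594 ± 38.3 CPM. Glia markers had 7 higher and 4 lower of 19 (camera adjusted p = 0.596), and optic lobe genes 2 higher and 3 lower of 17, with a median of 0.03 and a test direction downward (camera adjusted p = 0.865). Insulin and FOXO genes had 5 higher and 6 lower of 17, with a median of −0.16 and a mean of 0.16 (camera adjusted p = 0.545). Immune genes had 4 higher of 8 (camera adjusted p = 0.458, fry adjusted p = 0.0114). Dosage compensation and sex determination genes had 3 higher and 5 lower of 15, with a median of −0.21 and a mean of 0.08 (camera adjusted p = 0.458, fry adjusted p = 0.00456).

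Markers of tissues that a dissection can carry were measured as well. Of 15 muscle markers 9 rose and 1 fell (median 1.6, camera adjusted p = 0.00467, and adjusted p = 0.63 with an estimated correlation). The myosin light chain Mlc2 was at 5.97 ± 2.62 CPM in CDXY and 91.1 ± 22.4 in CDXX (SD, n = 3), and the list was not called without CDXX replicate 5 (adjusted p = 0.0726) or for its 11 members off X and 2L (adjusted p = 0.0901). Hemocyte markers had 3 of 14 higher (camera adjusted p = 0.149), namely the collagens Col4a1 (59.2 ± 45.4 to 473 ± 311) and vkg, and Hml, which reached 447 CPM in CDXX replicate 6 and was not called without it (adjusted p = 0.186). Salivary gland and cuticle markers had 6 lower and 2 higher of 11 (median −3.1, camera adjusted p = 0.0515, and 0.0126 with factors from genes off X and 2L, where the list in T2L had 0.0137). With an estimated correlation the list had adjusted p = 0.63 in CDXX and adjusted p = 0.858 in T2L. The glue gene Sgs4 was at 12.6 ± 6.09 and 0.729 ± 0.382 CPM. Fat body markers counted 1 higher and 2 lower of 10, with a median of −0.17 and a mean of 0.12 (camera adjusted p = 0.786). Eye-antennal disc markers counted 1 higher and 2 lower of 14, with a median of 0.16 and a test direction downward (camera adjusted p = 0.88), and ring gland and trachea markers 1 higher of 12 (camera adjusted p = 0.733). FDY, the one measured member of the list of Y-linked genes, was at 116 ± 12.1 CPM in Oregon, 101 ± 9.75 in CDXY and 89.4 ± 4.4 in CDXX. It does not follow the stated Y chromosome, and since FDY is a copy of an autosomal gene its reads cannot be taken as expression from Y.

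**Figure D2:**
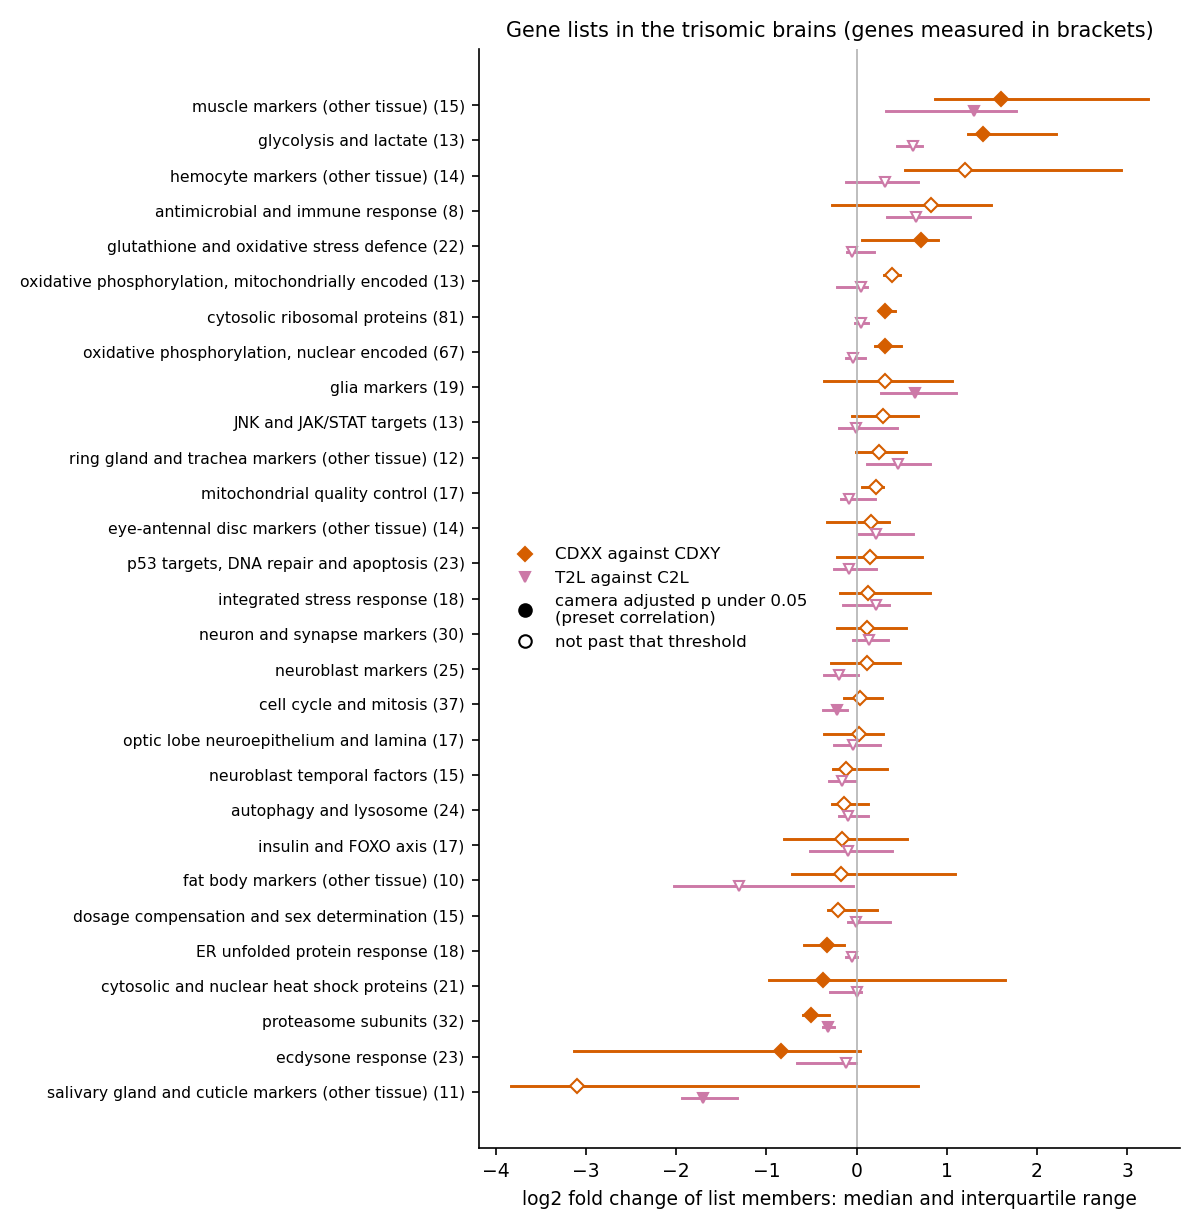
Log2 fold change of the members of 29 gene lists in CDXX against CDXY and in T2L against C2L, with the median as a symbol, the interquartile range as a line and the number of measured genes in brackets; filled symbols mark a camera adjusted p under 0.05 with the preset correlation, a mark that no list keeps with an estimated correlation. Proteasome subunits lie below 0 in both comparisons (medians −0.51 and −0.32), and glycolysis lies at 1.4 in CDXX and 0.62 in T2L.

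T2L against C2L asks how larval brains with an extra left arm of chromosome 2 differ from those without it, also at another age. Genes on 2L stood 1.46-fold above the others in T2L, a difference of medians of 0.55, with 0.547 ± 0.018 within batches (SD, n = 3 batches). Of 1562 genes on the arm 810 rose, 1 fell and 95.6% had a log2 fold change above 0 (camera adjusted p = 1.4e-74, and adjusted p = 8.44e-09 with an estimated correlation). Off the arm, 234 genes rose and 363 fell among 7419. The genes changed in T2L against C2L numbered 1408 (edgeR QL, BH adjusted p under 0.05), 1044 higher and 364 lower. Of these 252 changed by at least 2-fold. Factors from genes off X and 2L gave 1396 calls, 1234 higher and 162 lower, which put 88.4% of calls higher instead of 74.1%. The count fell to 755 without C2L replicate 6, to 927 without T2L replicate 4 and to 938 without T2L replicate 5.

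The largest rises in T2L included the cytochrome P450 gene Cyp6a17, which had no count in C2L and 22.2 ± 8.94 CPM in T2L (SD, n = 3), at least 576-fold higher. They also included Bbd (0.427 ± 0.151 to 13.1 ± 3.7 CPM), CG6912 (2.22 ± 0.366 to 49.1 ± 4.96), the peroxidase Irc (5.34 ± 0.382 to 40.1 ± 30.9) and the cuticle protein gene Cpr51A (2.4 ± 0.507 to 18 ± 10.7). Oregon held 13 ± 5.88 CPM of Cyp6a17 and 35 ± 5.21 of CG6912, so C2L was low in both. CG6912 (FBgn0038290, 3R, 15135138 to 15137004) rose by 4.46 on the log2 scale with a standard error of 0.18 (edgeR QL adjusted p = 3.2e-08), and its end overlaps that of the neighbouring gene asRNA:CR45600 by a few bases on the same strand. The largest falls included the protease-family gene CG6592 (11.6 ± 2.7 to 3.67 ± 0.362 CPM), CG4872 (8.56 ± 0.839 to 2.86 ± 0.437), the myosin gene Myo28B1, the storage protein gene Lsp1gamma and the lipid droplet protein gene Lsd-1. Oregon held only 0.331 ± 0.0272 CPM of CG6592 and 0.369 ± 0.0143 of Myo28B1, below T2L, so these falls start from a high level in C2L. The call of Myo28B1 in T2L against C2L ended without T2L replicate 5 (adjusted p = 0.0634), and the value of Lsp1gamma in T2L against C2L was −1.24 without C2L replicate 6 (adjusted p = 0.149).

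In T2L, lists with several called genes mostly held them on 2L. Of 67 nuclear genes of oxidative phosphorylation 13 rose, all on 2L, such as ND-15 (55.7 ± 2.22 to 91.8 ± 5.27 CPM, SD, n = 3), and 1 fell, with a median of −0.04 and a mean of 0.06 (camera adjusted p = 0.738). Ribosomal protein genes had 14 higher, 13 of them on 2L, such as RpL9 (1270 ± 137 to 2010 ± 118), and 1 lower of 81 (camera adjusted p = 0.0777). With factors from genes off X and 2L this list was called (camera adjusted p = 0.0389). It was not with an estimated correlation (adjusted p = 0.974) or for its 51 members off X and 2L (camera adjusted p = 0.888). The 3 that rose in each of the autophagy and lysosome list (Lamp1, Npc2a, ref(2)P), the endoplasmic reticulum list (CaBP1, Herp, Der-1), the JNK and JAK/STAT list (Socs36E, bsk, chinmo) and the mitochondrial quality control list (ClpP, Drp1, Phb1) lay on 2L. The 4 that rose among dosage compensation genes also did, msl-2 among them (38.9 ± 2.76 to 59.2 ± 3.68 CPM). Those 5 lists had camera adjusted p values of 0.873, 0.887, 0.612, 0.985 and 0.63, and the counts that fell in them were 1, 0, 0, 1 and 1. In each of these 5 lists the median lay below 0 and the mean above it.

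Proteasome subunits had a lower list in T2L as in CDXX. In T2L 3 of 32 fell and 1, Prosalpha6 on 2L, rose, whereas 20 fell and 1 rose when adjusted over the list alone, and 1 fell with factors from genes off X and 2L (median −0.32, camera adjusted p = 6.56e-06, and adjusted p = 0.858 with an estimated correlation). Rpn2 in T2L against C2L went from 420 ± 37.5 to 303 ± 24.2 CPM (SD, n = 3, edgeR QL adjusted p = 0.0127). Its adjusted p was 0.0548 without T2L replicate 4 and 0.0505 without C2L replicate 5. Cell cycle genes also had a lower list (median −0.22, camera adjusted p = 0.00844, and adjusted p = 0.858 with an estimated correlation), with 1 of 37 called, the lower Mcm2, whereas factors from genes off X and 2L gave 1 higher and none lower. The list was not called without C2L replicate 4 (adjusted p = 0.0642) or C2L replicate 6 (adjusted p = 0.101). Glia markers had a higher list, with 4 of 19 called, 7 when adjusted over the list alone, among them nrv2 (201 ± 44.3 to 446 ± 78.2 CPM, on 2L) and wrapper (87 ± 4.62 to 113 ± 5.5). Their median was 0.65 (camera adjusted p = 0.0167, and adjusted p = 0.858 with an estimated correlation), and the list was not called without T2L replicate 4 (adjusted p = 0.188), without C2L replicate 6 (adjusted p = 0.126) or for its 12 members off X and 2L (adjusted p = 0.153).

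Glycolytic genes had a median of 0.62 in T2L and none of 13 was called (camera adjusted p = 0.0777). Ldh was at 39.7 ± 25.8 CPM in C2L and 110 ± 10.8 in T2L (SD, n = 3). No ecdysone gene of 23 was called (median −0.12, camera adjusted p = 0.122), and neither was any of 25 neuroblast markers (0.0905), 17 optic lobe genes (0.577), 22 glutathione genes (0.761), 13 mitochondrially encoded genes (0.63) or 14 eye-antennal disc markers (0.875). The heat shock list had 1 higher, stv, and 1 lower, Hsp67Ba, of 21 (median near 0, mean 0.17, camera adjusted p = 0.25). Integrated stress response genes had 3 higher and 1 lower of 18 (0.629), p53 and repair genes 2 higher of 23 (0.629), temporal factors 1 higher and 1 lower of 15 (0.399), neuron markers 2 higher of 30 (0.314), insulin and FOXO genes 2 higher of 17 (0.632) and immune genes 2 higher of 8 (0.0777). Of the other-tissue lists, muscle markers had 3 higher of 15 (median 1.3, camera adjusted p = 0.0463, and adjusted p = 0.858 with an estimated correlation), with Mlc2 at 4.47 ± 1.42 CPM in C2L and 23.8 ± 10.6 in T2L, not called without C2L replicate 6 (adjusted p = 0.0525). The muscle list was not called with factors from genes off X and 2L (adjusted p = 0.0625), for its 11 members off X and 2L (adjusted p = 0.153), or without C2L replicate 4 (adjusted p = 0.184), T2L replicate 4 (adjusted p = 0.188) or C2L replicate 6 (adjusted p = 0.0745). Salivary gland and cuticle markers had none of 11 called (median −1.7, camera adjusted p = 0.0469, and adjusted p = 0.858 with an estimated correlation). That list was not called without T2L replicate 4 (adjusted p = 0.188), C2L replicate 5 (adjusted p = 0.1) or T2L replicate 6 (adjusted p = 0.0775). Fat body markers had 1 lower of 10 (0.0777), hemocyte markers 2 higher of 14 (0.544) and ring gland and trachea markers 1 higher of 12 (0.738). The fat body list was called with factors from genes off X and 2L (0.0389) and not with an estimated correlation (0.858). Bracketed values here are camera adjusted p. Median and mean had opposite signs in the optic lobe, glutathione, mitochondrially encoded and insulin lists, each of them within 0.1 of 0.

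The overlap of the 2 comparisons, which share no library, asks which changes they have in common. Both set brains taken 8 days after egg laying against controls taken 5 days after, and shared days pair libraries across them. A shared change can therefore come from age or stage as well as from an extra arm, and the counts for independent lists are only a reference. In both, 277 genes rose and 141 fell, where independent lists would give 241 and 75.8, and 296 went opposite ways against 301. Among the 5855 genes off X and 2L, 88 rose in both against 29.9, 139 fell in both against 69.9 and 20 went opposite ways against 91.4. Across genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.399 and a Spearman correlation of 0.29, with 0.432 and 0.415 off X and 2L and Pearson values of 0.308, 0.397 and 0.216 in the 3 batches. The genes that rose furthest in both were the iron transport protein gene Tsf1 (72.3 ± 21.8 to 1800 ± 321 CPM in CDXX and 83.5 ± 44.9 to 492 ± 243 in T2L, SD, n = 3), CG6357, Irc, Bbd and Cyp6a17. Against Oregon, T2L was higher for Tsf1, Irc and Bbd (edgeR QL adjusted p = 0.0019, 0.0263 and 0.00852). It was not for CG6357 (log2 fold change −0.33, adjusted p = 0.666) or Cyp6a17 (0.764, adjusted p = 0.426). Every C2L library of CG6357, Bbd and Cyp6a17 lay below all Oregon and CDXY libraries. The rises of those genes in T2L may therefore go back in part to the C2L stock. The genes that fell furthest in both comparisons were the receptor-like gene otk (383 ± 45.5 to 197 ± 16.9 in CDXX and 415 ± 56.8 to 285 ± 34.4 in T2L), Hsp67Ba, GstZ2, CG12259 and ClpX, the chaperone part of a mitochondrial protease. Without T2L replicate 4 the calls of Hsp67Ba, CG12259, ClpX and GstZ2 in T2L against C2L ended (adjusted p = 0.148, 0.0529, 0.105 and 0.0547), and without T2L replicate 5 that of otk in T2L against C2L did (adjusted p = 0.055). The genes shared in direction went from 418 to 199 without C2L replicate 6, to 219 in a fit of the compared groups alone and to 59 with the ecdysone covariate.

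**Figure D3:**
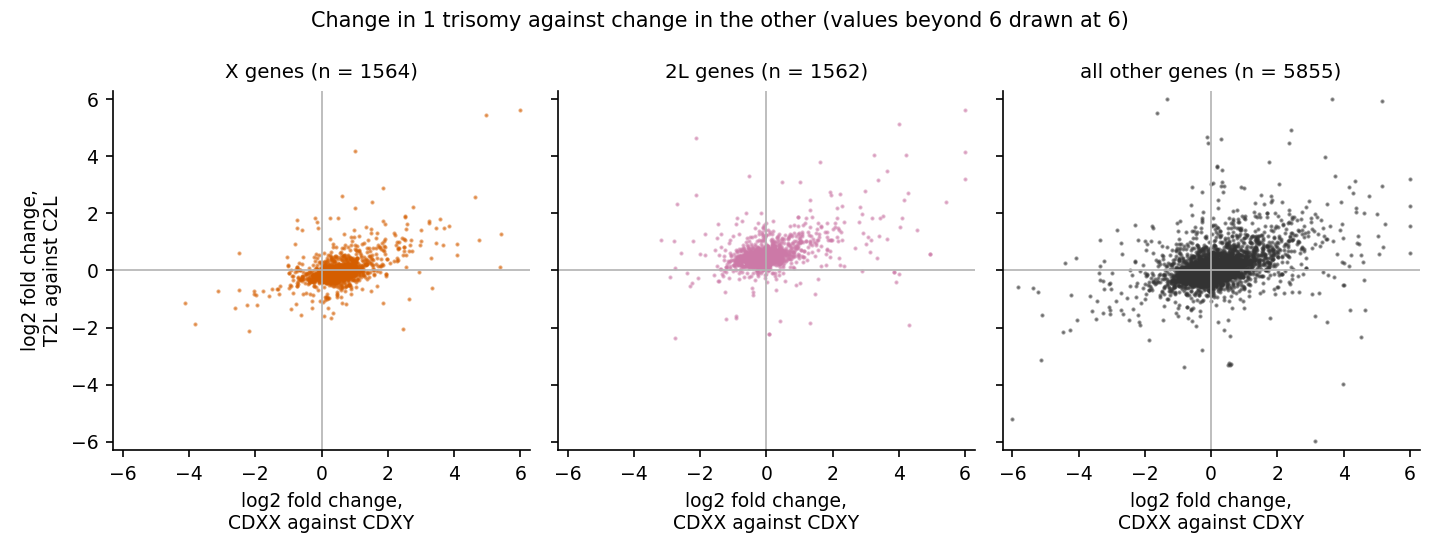
Log2 fold change of each tested gene in CDXX against CDXY (horizontal) and T2L against C2L (vertical), in separate panels for 1564 genes on X, 1562 on 2L and 5855 elsewhere; values beyond 6 are drawn at 6. X genes shift to the right and 2L genes upward, and the other genes lie along a rising diagonal with a Pearson correlation of 0.432.

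The difference between the trisomies was tested as a contrast of both comparisons. It was past the threshold for 2004 genes (edgeR QL, BH adjusted p under 0.05), 946 with a higher and 1058 with a lower fold change in CDXX, and 541 of them by at least 2-fold. Nuclear genes of oxidative phosphorylation had the higher fold change in CDXX in 25 of 67 and the lower in 1 (median of the difference 0.30, camera adjusted p = 5.3e-06, and adjusted p = 0.871 with an estimated correlation). Ribosomal protein genes (18 higher and 2 lower of 81, adjusted p = 8.57e-05), glutathione genes (7 higher of 22, adjusted p = 0.00318) and glycolytic genes (1 higher of 13, adjusted p = 0.042) lay on the same side in camera. The unfolded protein response list lay on the other (1 higher and 8 lower of 18, adjusted p = 0.00525), and each of the 5 lists had an adjusted p of 0.871 with an estimated correlation. Proteasome subunits did not pass as a list in this contrast (adjusted p = 0.216). The single genes with the largest differences included AOX1 (5.51 ± 1.59 to 180 ± 81 CPM in CDXX and 7.7 ± 5.44 to 17.6 ± 7.4 in T2L, SD, n = 3), whose adjusted p of 0.0156 became 0.0518 without C2L replicate 4.

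Comparisons with Oregon set the rearranged stocks against a standard strain. CDXY differed from Oregon in 77 genes, 29 higher and 48 lower, and C2L in 192, 81 higher and 111 lower (edgeR QL, BH adjusted p under 0.05). Neither X nor 2L stood apart in them, with differences of medians between 0.00276 and 0.0205. CDXY had more lncRNA:CR42646 (1.97 ± 0.365 CPM in Oregon and 14.6 ± 1.49 in CDXY, SD, n = 3), CG9360 and the receptor phosphatase gene Ptp10D (151 ± 21.8 to 342 ± 22.2), and less CG3603 (10.4 ± 1.61 to 2.14 ± 0.684) and lncRNA:CR34335 (2540 ± 640 to 858 ± 65.3). C2L had more mthl8 (0.048 ± 0.0831 to 52.7 ± 5.49 CPM), Ssk (0.657 ± 0.275 to 18.6 ± 3.74), CG6592 and Myo28B1. It had less Arc1, a retrotransposon-derived capsid gene (421 ± 52.8 to 58.1 ± 11.3), its neighbouring pseudogene CR10102, CG6912 and Cyp6a17, the last at least 339-fold lower. Reads of Arc1 and CR10102 may be shared. Glycolytic genes were lower as a list in both stocks (medians −0.81 and −0.59, camera adjusted p = 5.87e-05 and 0.0201), with none of 13 genes called in edgeR. Both comparisons use the same Oregon libraries, whose glycolysis scores were 7.13, 7.69 and, in replicate 6, 8.71. The scores ran from 6.93 to 7.54 in CDXY and from 7 to 7.93 in C2L, so much of this difference rests on Oregon replicate 6. In CDXY, nuclear oxidative phosphorylation genes (median −0.17, camera adjusted p = 2.67e-07) and cell cycle genes (median −0.21, 0.00251) were also lower as lists, and ecdysone genes (median 0.25, 0.0347) and salivary gland and cuticle markers (median 0.66, 0.0404) higher, with no gene of these lists called. The ecdysone score ran from 5.77 to 6.25 in CDXY and was 5.96, 5.62 and, in replicate 6, 4.83 in Oregon. Much of the ecdysone difference therefore rests on that Oregon library. In C2L, neuron markers (median −0.20, 0.0201) and glia markers (median −0.35, 0.0201) were lower, with 1 gene called lower in each, and fat body markers (median 1.2, 0.0319) higher with none called. Each list of CDXY had an adjusted p = 0.995 with an estimated correlation and each list of C2L an adjusted p = 0.98 with an estimated correlation. The 77 genes went to 47 without Oregon replicate 6 and to 14 in a fit of the compared groups alone, and the 192 genes to 121 without C2L replicate 6 and to 109 in such a fit.

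The genes changed in CDXX against Oregon numbered 3173 (1680 higher, 1493 lower) and the genes changed in T2L against Oregon 1166 (925 higher, 241 lower) in the edgeR QL test. X genes stood 1.47-fold above the others in CDXX and 2L genes 1.46-fold in T2L. With factors from genes off X and 2L the calls were 2069 higher and 892 lower in CDXX and 1131 higher and 101 lower in T2L. Proteasome subunits were lower again, with 25 of 32 in CDXX (median −0.51, camera adjusted p = 4.14e-09, and adjusted p = 0.708 with an estimated correlation) and 2 lower and 1 higher in T2L (median −0.24, camera adjusted p = 0.000421, and adjusted p = 0.993 with an estimated correlation). Ribosomal protein genes counted 33 higher of 81 in CDXX and nuclear oxidative phosphorylation genes 17 of 67 (camera adjusted p = 3.93e-10 and 0.00104, and adjusted p = 0.781 with an estimated correlation for both). Ecdysone genes did not pass in CDXX against Oregon (2 higher and 5 lower of 23, median −0.41, camera adjusted p = 0.161), nor did glia markers in T2L against Oregon (0 of 19 called in edgeR, median 0.14, camera adjusted p = 0.618). The median of nuclear oxidative phosphorylation genes in CDXX was 0.15 against Oregon and 0.32 against CDXY. Glycolytic genes counted 2 higher of 13 against Oregon, where 12 were higher against CDXY (median 0.57, camera adjusted p = 0.0316, and adjusted p = 0.781 with an estimated correlation).

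**Figure D4:**
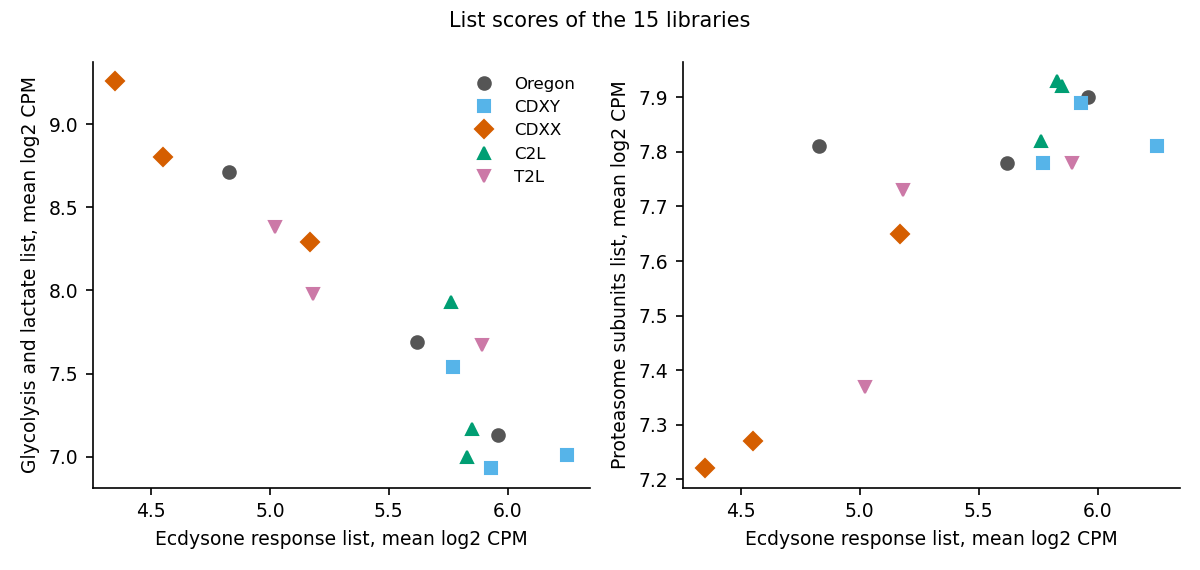
Mean log2 CPM of the ecdysone list (horizontal) against that of the glycolysis and of the proteasome lists (vertical) in each of the 15 libraries, coloured by group. CDXX libraries lie at low ecdysone scores (4.35 to 5.17) with glycolysis scores of 8.29 to 9.26, and Oregon replicate 6 (4.83 and 8.71) and T2L replicate 4 (5.02 and 8.38) lie within both ranges.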

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

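Glycolytic genes stood out in CDXX, where 12 of 13 rose with a median log2 fold change of 1.42 (SE 0.41), against none called in T2L. SE beside a list median is the median standard error of its single genes, not the standard error of that median. The test of hormone stage was written before its result was seen and the test of muscle after. With the ecdysone score as a covariate the glycolysis median became 0.0367 (SE 0.35) with 0 genes called, and it lay between −0.193 and 0.179 when each library was left out. Within groups the ecdysone and glycolysis scores had a Pearson correlation of −0.858 (n = 15, two-sided permutation p = 0.00062, adjusted p = 0.0019 over 3 relations, −0.813 without the 2 farthest libraries), so a younger or older hormone stage of the larvae may account for the rise, although this score is itself confounded with genotype and age. The other explanation was muscle carried over with the brains. With all its genes the muscle list rose by 3050 CPM, 52.2% of the glycolytic rise of 5840 CPM. Most of this was Msp300, which was at 1760 to 2350 CPM in Oregon brains, where Mlc2 was at 2.7 to 13.6. Without Msp300 and Tm1 the muscle rise was 213 CPM, or 3.64%. The score of those 13 remaining genes had a correlation of 0.142 with glycolysis (permutation p = 0.67, adjusted p = 0.67). The test asked for a small share both with and without Msp300 and Tm1, which the whole list did not meet, so the test could not decide. Taken alone, and as far as they report muscle, the 13 genes argue against it as the main source of the glycolytic rise. A smaller share stays open.

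Genes off 2L that changed at least 2-fold in T2L against C2L numbered 148, among them Cyp6a17 and CG6912, which were also low in C2L against Oregon. The test of alleles in the C2L stock was written after values had been seen, and its counterpart before. In 43.2% of them (64 of 148, Wilson interval 35.5 to 51.3) every C2L library lay outside all Oregon and CDXY libraries on the side away from T2L, whereas CDXY lay outside Oregon and C2L in 5.28% (38 of 720, 3.87 to 7.16) of such genes in CDXX against CDXY. Both sets of genes were chosen by their difference from these same control libraries, which by itself favours controls that lie outside. The 2 comparisons also differ in strength, so their shares are only described. Only 24.3% (36 of 148, 18.1 to 31.8) were also called in T2L against Oregon, as a change in the T2L brains themselves would ask. A gene not called there may still differ. Alleles or deletions carried by the C2L stock could therefore explain part of these genes, such as the missing counts of Cyp6a17 in C2L, and the data cannot separate them from an effect of the extra arm for the rest.

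Proteasome subunits had medians of −0.505 (SE 0.13) in CDXX, with 24 of 32 called lower, and −0.32 (SE 0.13) in T2L, with 3 lower and 1 higher, a fry adjusted p of 0.207 and a camera adjusted p = 0.858 with an estimated correlation. SE is again the median standard error of the single genes. The scaling test was written after the result was seen and the hormone stage test before. With factors from genes off X and 2L the medians were −0.419 and −0.257, so a shift from the extra arm is unlikely to produce them. With the ecdysone score as a covariate they became −0.171 (SE 0.17) and −0.223 (SE 0.12). The CDXX value lay between −0.389 and −0.00862 when each library was left out, the latter without Oregon replicate 6. Hormone stage might carry part of the CDXX fall, since the scores had a correlation of 0.653 within groups (n = 15, two-sided permutation p = 0.036, adjusted p = 0.054). Oregon replicate 6 went the other way, with a low ecdysone score (4.83) and a proteasome score of 7.81. The other Oregon libraries had 7.9 and 7.78, and CDXX libraries 7.27, 7.65 and 7.22. Against Oregon the CDXX proteasome median was −0.51, where ecdysone genes did not pass (median −0.41, camera adjusted p = 0.161). The data cannot tell how much hormone stage carries.

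Regrouping the libraries asked whether grouping alone gives such counts, a test set before the result was seen. Every other split of 6 libraries mixes the 2 groups compared, so their real differences widen the spread within groups and few calls can arise. Counts of 0 in those splits therefore cannot decide the question. Of the 10 splits of 6 libraries into 3 and 3, only 1, the real one, called any gene in each of the 6 comparisons (3942, 1408, 77, 192, 3173 and 1166 genes, highest other 0), and 10 splits are too few for a share under 0.05. Since batch labels pair libraries, the fitting comparison is with the 3 other splits that part all 3 batches, fewer still, where the highest other was 0 genes, and 10 lists in either main comparison. The counts of lists did not stand out, with 5 of 10 splits calling as many in CDXX (9 lists, highest other 10) and 9 of 10 in T2L (5 lists, highest other 11). In 100 joint regroupings, which did not keep the batches together, 2 had as many genes in the difference (2004, highest other 3544). Only 1, the real one, had as many shared genes (418, highest other 296). The 3544 and the 296 both came from the real grouping with T2L and C2L exchanged.

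The difference between the trisomies covered 2004 genes, and the largest named ones were not alike. CG42500 (9.10) and Lcp1 (7.93) rested on CDXX replicate 5, without which the adjusted p was 0.447 for CG42500 in difference and 0.367 for Lcp1 in difference. Cpr78E (3.99) kept its call without each library, and AOX1 (3.84) lost it without C2L replicate 4 (3.11, adjusted p = 0.0518 for AOX1 in difference). The P450 gene Cyp6a17 had no fold change to give, with an adjusted p of 0.0117, and asRNA:CR45600 (−4.80), next to CG6912, was at 0.345 CPM in C2L against 7.25 in Oregon and 8.96 in T2L, which may go back to the C2L stock, where 43.2% of such genes stood apart. Spn100A (−4.76) and Cht5 (−4.67), which fell in CDXX alone, lost their calls in 11 and 8 alternatives. Among lists the camera adjusted p of the difference was 0.00525 for the unfolded protein response, 0.00318 for glutathione, 5.3e-06 for nuclear oxidative phosphorylation, 0.042 for glycolysis and 8.57e-05 for ribosomal proteins, and adjusted p = 0.871 with an estimated correlation for each.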

How the results depend on the processing

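Gene counts held within 1.5-fold in most alternatives. Genes at least 1 on the log2 scale numbered 957 in CDXX against CDXY, 252 in T2L against C2L, 35 in CDXY, 100 in C2L, 649 in CDXX and 183 in T2L against Oregon, and 541 in the difference. With an estimated correlation camera called 0 lists in CDXX and 0 in T2L, and with members off X and 2L alone 3 in T2L. A fit of the compared groups alone gave 219 shared genes and 14, 109, 1877 and 563 changed genes for CDXY, C2L, CDXX and T2L against Oregon. The Wald test of DESeq2 gave 176 and 356 genes for CDXY and C2L against Oregon and 662 shared genes. With batch as a block the counts were 4218 in CDXX against CDXY, 1653 in T2L against C2L, 94, 214, 3437 and 1371 against Oregon (CDXY, C2L, CDXX, T2L), 2418 in the difference, and 532 genes changed in the same direction in CDXX against CDXY and T2L against C2L. The ecdysone covariate, added after the values were seen, left 416 genes in CDXX against CDXY, 59 shared genes and 2 lists in T2L, and it turned Gad1 in CDXX against CDXY to −0.0922 and Shab in CDXX against CDXY to −0.111. That 416 was itself unsteady, from 4 to 446 with each library left out. Leaving out each library gave 755 (without C2L replicate 6) to 1151 genes (without T2L replicate 6) in T2L against C2L, 47 to 65 in CDXY and 121 to 171 in C2L against Oregon, and 199 (without C2L replicate 6) to 433 shared genes (without T2L replicate 6). The correlation across genes lay between 0.305 (without T2L replicate 4) and 0.461 (without C2L replicate 4), and between 0.341 and 0.5 off X and 2L. Lists called in T2L ranged from 2 (without T2L replicate 4) to 8 (without T2L replicate 6).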

Other observations

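Genes encoded in the mitochondrial genome had a median log2 fold change of 0.43 over 18 genes in CDXX (camera adjusted p = 0.0243, and adjusted p = 0.594 with an estimated correlation). Of these 18 genes 6 rose and none fell.

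The ecdysone score, which does not measure stage itself, differed between replicates. Oregon replicate 6 had an ecdysone score of 4.83 against 5.96 and 5.62 in the other Oregon libraries, and its glycolysis score of 8.71 lay within the range of CDXX. The first component held 36.9% of the variance. T2L replicate 6 had an ecdysone score of 5.89, near the C2L libraries, against 5.02 and 5.18 in the other T2L libraries, and leaving it out raised the lists called in T2L to 8. The ring gland score ranged from −1.41 to 7.59 over libraries, which may mean that the gland was carried with some brains and not others, and a covariate for it left 3859 changed genes in CDXX and 1335 in T2L.

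X genes stood 0.53 above the other genes on the log2 scale in CDXX and 2L genes 0.55 in T2L, as differences of medians, where 3 copies against 2 give 0.585. Age differed together with genotype in both. Larvae of all 4 stocks at one hormone stage, with C(2L)SH1 and its trisomic brood in one genetic background, would separate the extra arm from stage and from alleles of the stock. The Y chromosome would still differ between CDXY and CDXX.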
